A study of Mus musculus with 4 samples.

How the data were processed

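Spatial gene expression was measured with 10x Genomics Visium in cryosections of fresh-frozen tibialis anterior muscle from C57BL/6 mice of 24 months (old) and 5 months (young). There were 2 samples per age, and each sample was 1 of 4 capture areas. Old samples 1 and 2 and young sample 2 held 2 sections each and young sample 1 held 1 section, so that 7 matrices were used, 4 old and 3 young. Per the labels, both old samples and young sample 2 came from 2 different mice each. The labels do not tie a section to a mouse, and the number of mice behind young sample 1 was not given in the sources used here. Each capture area held 1 age only and was the replicate. Ages were thus compared against the spread between capture areas of an age, estimated in part from other genes.

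The deposited matrices held whole-number UMI counts per gene and spot, not normalized, for 32285 features and 7685 spots. The UMI counts were made with Space Ranger against mm10, per the submitters' processing notes. The Space Ranger version, its settings and the gene annotation were not given in the sources used here. The spots in the deposited count matrices equalled in number those marked as tissue in the slide alignment of each section. That alignment lists 4992 grid positions per capture area without barcodes, so spot positions were not used here. The 38 symbols shared by more than 1 feature were kept apart by their Ensembl identifiers. Visium counts come from the 3' end of transcripts by poly(A) capture, and near-identical genes can share reads. Genomic positions are those of the RefSeq annotation of GRCm38.p6, the assembly that mm10 names.

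Counts were summed per sample over all spots, because spots are not replicates. Total counts were 5146924 and 5946737 UMIs in old samples 1 and 2, and 3818766 and 10150723 in young samples 1 and 2. A gene with 0 UMIs therefore allows up to 0.786 CPM (3 counts, scaled to the total of the sample) in the shallowest sample and 0.296 in the deepest. Intervals from counts cover counting error only. The 2 sections of a capture area differed by more than sampling noise, with a chi-square per degree of freedom of 3.43 in old sample 1, 6.48 in old sample 2 and 4.58 in young sample 2, so none was a repeat of another. Levels are given as CPM, counts scaled to a common library total, after TMM scaling, as mean ± SD over the 2 samples of an age.

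Old and young were compared with edgeR's quasi-likelihood test on the summed counts, with TMM normalization, the filterByExpr filter (minimum count of 10, minimum total of 15), Benjamini-Hochberg adjustment and a threshold of 0.05. The TMM factors lay between 0.870 and 1.11. The test moderates the variance of each gene toward a trend over all genes. In whole sections it had 9.30 prior degrees of freedom beside the few residual ones of 4 samples. A gene whose own samples lie far apart can therefore pass. Fibre zones were set from the myosin heavy chain counts of each spot. Spots with at least 500 UMIs and at least 20 UMIs over Myh1, Myh2, Myh4 and Myh7 were ranked within each matrix by the Myh4 share of these UMIs. The upper tercile was the Myh4-high zone and the lower tercile the Myh4-low zone. Counts were summed per sample and zone and tested in edgeR with the sample as a block, for the difference between zones and for the interaction of age with zone. The age effect within a zone was tested on the sums of that zone. The 4 myosin genes that define the zones were left out of the calls and of the gene lists between zones.

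Before the data were examined, 32 gene lists were fixed. They were polyamine metabolism, polyamine transport and eIF5A hypusination, methionine cycle and salvage, fast-twitch sarcomere, slow-twitch sarcomere, calcium handling, glycolysis, fatty acid oxidation, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, collagens and extracellular matrix, denervation response, neuromuscular junction, atrophy, integrated stress response, senescence, antigen presentation and interferon response, circadian clock, immediate early and heat shock genes, sex-linked genes and cytosolic ribosomal proteins. Markers of macrophages, B and plasma cells, T and natural killer cells, adipocytes, tendon, fibro-adipogenic progenitors, endothelium, smooth muscle and pericytes, Schwann cells and nerve, satellite cells and red blood cells made up the others. A list with at least 3 measured genes was tested with limma's camera on log2 CPM (prior count of 2), which compares a list with all other genes, at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry, which asks only whether a list's genes move one way on balance, were run beside it. Camera with an estimated correlation rests on the few residual degrees of freedom that so few samples leave. A lack of calls in that form therefore cannot decide for or against a list. Of the 32 lists, 31 could be tested in whole sections.

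The comparisons, their tests and the rule for named genes were also fixed before the data were examined. The named genes are the 10 largest rises and 10 largest falls past the threshold with a mean of at least 20 CPM and no overlap between the ages, without symbols of predicted genes. All measured genes of the polyamine metabolism list were named, and the 3 genes of lowest p from each list with 3 or more calls. Between zones, the 8 largest differences each way were named, within zones the 5 largest age effects each way, and all genes with an interaction if there were 10 or fewer. Other genes named for a list with few calls were chosen after their values were seen. Some genes that these rules take are not reported here. Regions are Leiden clusters of 7655 spots with at least 500 UMIs (2000 variable genes, 20 principal components, 15 neighbours, resolution 0.5), which left out 30 spots. They are named by the 5 genes with the highest fold against all other spots and a mean of at least 0.1 UMIs per spot. Their shares are given without a test, and spots were not assigned to cell types.

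Alternatives fixed before the data were examined were DESeq2's Wald test, DESeq2's size factors in edgeR, library size alone, other filters on low counts, the replicate number as a block, each sample left out in turn, sections as replicates, and sections in limma voom with the capture area as a random block. Further ones changed the genes in the library size, the spots used, the depth (each sample thinned to 3818766 UMIs), the scaling of each spot to 1 total (tested in limma), the zone limits and the clustering. After the data were seen, 4 were added: spots matched on the Myh4 share (980 spots per sample over 10 deciles of the share) for genes and for lists, old sample 1 without its second section, and the zones within each age alone.

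The tests were run on simulated counts with known changes. For old against young in whole sections (10874 simulated genes), 92 percent of 100 genes with a true change of 1 log2 unit and 22 percent of 100 with 0.5 were recovered, with 10 false calls. Between zones (8155 genes) the shares were 100 and 78 percent, with 7 false calls, and for the interaction (8965 genes) 85 and 22 percent, with 4. For the age effect they were 85 and 20 percent in the Myh4-high zone (7953 genes, 8 false calls) and 80 and 8 percent in the Myh4-low zone (8554 genes, 3 false calls). Most single-gene changes of 0.5 log2 units with age would therefore be missed. The changed genes were drawn from those with higher counts, so recovery among genes of low counts was not measured. In simulated data with 1 of 30 lists shifted by 0.5 log2 units, camera ranked that list 1 and called 0 others. Genes were simulated independently of each other, so this could not test the preset inter-gene correlation. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, scipy 1.17.1, numpy 2.4.6 and matplotlib 3.10.9 were used.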

Results

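Spatial transcriptomes were measured in sections of the tibialis anterior, a fast-twitch muscle of the hindlimb, from C57BL/6 mice aged 24 months (old) or 5 months (young). In the Visium assay a section lies on a grid of barcoded capture spots, each of which can cover parts of several fibres and the cells between them, and unique molecular identifiers (UMIs) count the captured mRNA molecules. Each age had 2 samples, with 4 old and 3 young sections in all. The old samples 1 and 2 gave 5146924 and 5946737 UMIs over 1913 and 2153 spots, and the young samples 1 and 2 gave 3818766 and 10150723 UMIs over 1097 and 2522 spots. Median UMIs per spot were 2506 and 2461 in the old samples and 3169 and 3750 in the young. Mitochondrially encoded transcripts took 30.0 and 31.9% of UMIs in the old samples and 33.4 and 37.8% in the young, and haemoglobin transcripts took 0.356 and 0.359% against 0.140 and 0.273%. Because the labels do not tie sections to single mice, p-values measure only the spread between these samples, part of which may be technical. That spread was estimated largely from all genes together, not from each gene alone.

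The make-up of adult myosin heavy chains differed between the ages. Myh4, the myosin of the fastest and most glycolytic fibres, made up 73.5% ± 0.192 (SD, n = 2) of the UMIs over Myh1, Myh2, Myh4 and Myh7 in old muscle and 61.5% ± 3.58 in young muscle. Myh1, of intermediate fast fibres, made up 23.5% ± 0.522 in old and 35.2% ± 2.4 in young muscle. Myh2, of fast oxidative fibres, made up 2.99% ± 0.304 against 3.26% ± 1.18, and Myh7, the slow myosin, 0.0340% ± 0.0256 against 0.0181% ± 0.00194. The Myh4 share of each old section, 72.3 to 74.9%, lay above that of each young section, 58.3 to 64.0% (two-sided exact permutation p = 0.0286 over 35 splits of the sections, whose independence is not given by the labels). Over the 2 samples per age the exact permutation p was 0.333, the smallest that 6 splits can give.

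**Figure D1:**
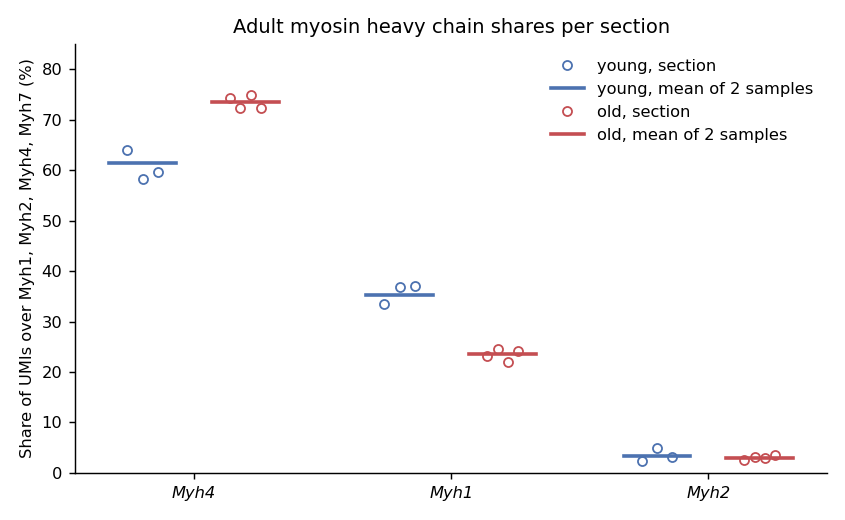
Share of each of Myh4, Myh1 and Myh2 in the UMIs over 4 adult myosin heavy chain genes (%), with open circles for the 4 old and 3 young sections and lines for the mean of the 2 samples per age. The Myh4 share lies at 72.3 to 74.9% in the old sections and at 58.3 to 64.0% in the young.

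Comparing old with young whole sections asked which transcripts differed with age in this muscle. Old muscle held more mRNA of the muscle-derived peptide osteocrin (Ostn), the secreted protein Dkk3, the carboxylesterase Ces1d and the ubiquitin ligase Mib1. It held far less of the exercise-responsive nuclear receptor Nr4a3, the metallothioneins Mt1 and Mt2, inducible heat shock proteins, the transferrin receptor Tfrc, the nicotinamide riboside kinase Nmrk2 and the fibrillar collagen Col3a1. Of 10840 genes tested, 184 rose and 258 fell in old muscle at an adjusted p under 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 2313 had an unadjusted p under 0.05. In all 442 genes the old and young samples did not overlap, against 51.5% of all tested genes and a chance share of 33.3%. The direction of calls depended on scaling: 41.6% were higher in old muscle with TMM, 40.4% (202 higher, 298 lower) with DESeq2's size factors in edgeR, 80.7% (419 higher, 100 lower) with library size alone and 81.4% (635 higher, 145 lower) with each spot scaled to 1 total in limma. In DESeq2, which changes the test as well as the scaling, 24.8% were higher (85 higher, 258 lower). Library size alone and the scaling of spots moved the median log2 difference of all genes from 0.016 to 0.265 and 0.228. A value near 0 that turns sign under these scalings can therefore reflect this common shift alone. The number of calls depended on which sample was left out. None of the called genes that could still be tested (440 to 442) changed sign when any sample was left out. Since the samples of the ages did not overlap in these genes, that outcome was nearly fixed beforehand.

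Ostn rose from 6.22 ± 3.35 to 39.6 ± 9.50 CPM (log2 2.84, SE 0.30, adjusted p = 5.9e-04), and the secreted Dickkopf family member Dkk3 from 10.7 ± 3.80 to 41.6 ± 4.88 CPM (log2 2.05, adjusted p = 6.5e-04). The glutathione-degrading enzyme Chac1 rose from 16.4 ± 1.94 to 52.7 ± 5.24 CPM (log2 1.66, adjusted p = 5.0e-04), but its 4 old sections lay at 46.3, 68.3, 13.5 and 86.4 CPM, 1 of them within the young range of 11.3 to 24.2. The ubiquitin ligase Mib1, which acts on Notch ligands, rose from 35.2 ± 1.95 to 88.3 ± 0.0354 CPM (log2 1.32, adjusted p = 5.2e-04). The carboxylesterase Ces1d (log2 1.83), the glutathione transferase Gstm2 (log2 1.5) and the ADP-ribosyltransferase Art5 (log2 1.27) rose as well, at adjusted p of 0.0014, 5.8e-04 and 0.0078. Cyp26b1, which degrades retinoic acid, passed the test at log2 3.34 (SE 0.80, adjusted p = 0.042), but its old samples lay at 105 and 10.7 CPM. Its call was lost in DESeq2 (adjusted p = 0.158) and without old sample 1 (log2 0.93, adjusted p = 0.0925), young sample 1 (log2 3.26, adjusted p = 0.0797) or young sample 2 (log2 3.48, adjusted p = 0.197). Pfkfb3, a regulator of glycolytic flux, passed at log2 1.95 (adjusted p = 0.036), with old samples at 164 and 48.2 CPM and an old section at 26.9 CPM, within the young range of 14.9 to 36.3. Its log2 difference was 0.80 (adjusted p = 0.0097) without old sample 1, and its call was lost without young sample 2 (log2 1.55, adjusted p = 0.215) and in DESeq2 (adjusted p = 0.283).

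Nr4a3 fell from 73.4 ± 19.9 CPM in young to 5.10 ± 1.5 CPM in old muscle, a 14.0-fold difference (log2 -3.81, SE 0.25, adjusted p = 2.6e-05). Mt2 fell from 113.8 ± 10.3 to 13.2 ± 4.06 CPM (log2 -3.10) and its chromosome 8 neighbour Mt1 from 175 ± 32.8 to 36.3 ± 6.34 CPM (log2 -2.28), at adjusted p of 2.6e-05 and 6.2e-05. Nmrk2 fell from 353 ± 28.7 to 91.0 ± 6.23 CPM (log2 -1.95, adjusted p = 2.6e-05). Tfrc, which imports iron, fell from 86.4 ± 39.5 to 20.7 ± 0.448 CPM (log2 -2.09, adjusted p = 0.0014). The muscle LIM protein Csrp3 (log2 -1.64), the lysine methyltransferase Mettl21c (log2 -1.58) and the endothelin receptor Ednrb (log2 -1.5) fell, at adjusted p of 8.5e-04, 0.0014 and 6.8e-04. The heat shock genes Hspa1a and Hspa1b, near-identical neighbours on chromosome 17 between which reads can be shared, fell together (log2 -2.86 and -3.23, adjusted p of 0.0059 and 0.0024). Their young samples differed among themselves, at 18.8 and 58.9 CPM for Hspa1a, whose log2 difference was -1.73 (adjusted p = 0.0054) without young sample 2.

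In the polyamine metabolism list, the enzymes Amd1 and Smox were lower in old muscle. Amd1 (chromosome 10, 40287458 to 40302188, mm10) encodes S-adenosylmethionine decarboxylase, which supplies the aminopropyl groups of spermidine and spermine. It fell from 110.1 ± 8.31 to 47.3 ± 4.61 CPM (log2 -1.21, SE 0.14, adjusted p = 7.7e-04). Smox (chromosome 2, 131491858 to 131525183), the spermine oxidase, fell from 108 ± 9.82 to 39.0 ± 5.3 CPM (log2 -1.46, SE 0.15, adjusted p = 5.2e-04). Of 11 measured genes, 2 fell and 9 did not pass over all genes, and 4 fell when adjusted over the list alone. The other 2 were ornithine decarboxylase Odc1 (48.6 ± 6.08 to 33.4 ± 1.26 CPM, log2 -0.55, adjusted p = 0.063) and the antizyme inhibitor Azin1 (35.2 ± 0.394 to 23.9 ± 1.2 CPM, log2 -0.56, adjusted p = 0.061). The list as a whole had a median log2 of -0.24 and was lower in camera (adjusted p = 0.023), but with adjusted p = 0.772 with an estimated correlation and 0.214 in fry. Without young sample 1 its camera adjusted p was 0.132. Of 1000 random lists matched on expression and genomic length, 114 had as low a median.

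The remaining polyamine genes gave no call. Amd2 (chromosome 10, 35708691 to 35711891), a near-identical copy of Amd1, had a log2 difference of -0.49 (adjusted p = 0.27). The summed counts of Amd1 and Amd2, which do not depend on how reads were split between them, fell from 140.0 ± 19.1 to 67.8 ± 0.499 CPM (log2 -1.04, SE 0.14, adjusted p = 0.0021). Spermine synthase Sms (log2 -0.24), spermidine synthase Srm (log2 -0.046), the acetyltransferase Sat1 (log2 0.0015), the oxidase Paox (log2 0.49) and the antizymes Oaz1 (log2 -0.096) and Oaz2 (log2 0.28) had adjusted p of 0.258 or more, and the signs of Srm, Sms, Sat1 and Oaz1 turned under other scalings. In polyamine transport and eIF5A hypusination, edgeR called 0 of 7 genes (2 at an unadjusted p under 0.05), also adjusted over the list alone. DESeq2 called 0 of the 6 with an adjusted p there. The median log2 was -0.052, turning to 0.21 with library size alone (camera adjusted p = 0.703). In the methionine cycle and salvage, edgeR called 0 of 13 (3 at an unadjusted p under 0.05), also adjusted over the list alone. DESeq2 called 0 of the 9 with an adjusted p there. The median was 0.081 but the mean was -0.0061 and camera's direction was down (adjusted p = 0.731).

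**Figure D2:**
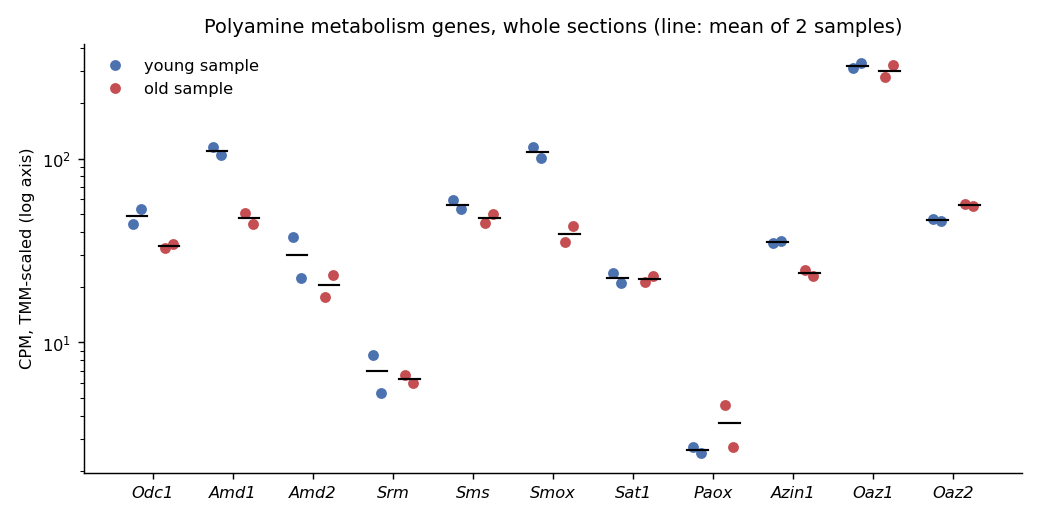
Level of the 11 measured polyamine metabolism genes in TMM-scaled CPM on a log axis, with a point per sample (2 old, 2 young) and a line for the mean of each age. The old samples lie at 44.1 and 50.6 CPM for Amd1 and at 35.3 and 42.8 CPM for Smox, below the young samples at 104 and 116 and at 101 and 115 CPM.

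Of 58 nuclear-encoded oxidative phosphorylation genes, 20 fell in old muscle and 38 did not pass over all genes, 49 fell when adjusted over the list alone, and all 58 had a log2 difference below 0 (median -0.48). The cytochrome oxidase subunits Cox7a1 (1883 ± 223 to 997 ± 53.6 CPM, log2 -0.92), Cox5b (log2 -0.72) and Cox7c (log2 -0.74) fell at adjusted p of 0.0046, 0.013 and 0.014. Without old sample 1 the adjusted p of Cox5b was 0.121 and that of Cox7c 0.176. Camera placed the list below other genes (adjusted p = 1.9e-17), with adjusted p = 0.772 with an estimated correlation. Genes of the same expression and genomic length also tended to be lower, with a random-list median of -0.26. Relative to the shift of all genes, the list's median was -0.51 with library size alone, and in spots matched on the Myh4 share it was -0.35.

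All 13 mitochondrially encoded mRNAs lay below 0 (median log2 -0.37), and 1 of them, mt-Atp8 (log2 -0.53, adjusted p = 0.039), fell, also when adjusted over the list alone, a call lost without old sample 1 (adjusted p = 0.323) or old sample 2 (0.26). Camera gave adjusted p = 8.5e-05 for that list and adjusted p = 0.772 with an estimated correlation. In fatty acid oxidation, 2 of 20 genes fell, the kinase Pdk4 (log2 -0.93, adjusted p = 0.0071) and the uncoupling protein Ucp3 (log2 -0.79, adjusted p = 0.025, and 0.168 without young sample 2). Adjusted over the list alone, 5 fell and 1 rose. Its median log2 was -0.25 (camera adjusted p = 0.019, and adjusted p = 0.788 with an estimated correlation), but -0.0041 in spots matched on the Myh4 share, where camera's adjusted p was 0.907. Its camera call was also lost without old sample 1 (adjusted p = 0.0844), without young sample 2 (adjusted p = 0.528) and among genes of at least 20 CPM (adjusted p = 0.159). In glycolysis and glycogen breakdown 1 of 16 genes, Gapdh, fell (log2 -0.55, adjusted p = 0.043, but 0.439 without old sample 1 and 0.206 without old sample 2), or 2 adjusted over the list alone. The median of this list was -0.25 (camera adjusted p = 0.023, and adjusted p = 0.772 with an estimated correlation), and its call was lost without old sample 1 (0.114) and young sample 1 (0.147), with library size alone (0.0835) and among genes of at least 20 CPM (0.159). Of 1000 matched random lists 217 had as low a median. Among 75 cytosolic ribosomal protein genes 4 fell, or 28 adjusted over the list alone, and 73 lay below 0 (median -0.30). Rpl10, Rps2 and Rps24 (log2 -0.54, -0.58 and -0.51) had adjusted p of 0.036, 0.036 and 0.042. Each of these 3 calls was lost without old sample 1 (adjusted p of 0.151, 0.232 and 0.273), without old sample 2 (0.153, 0.0883 and 0.267) and without young sample 2 (0.139, 0.118 and 0.0778), and with library size alone. Camera gave adjusted p = 2.4e-12 for the ribosomal list and adjusted p = 0.772 with an estimated correlation, and random lists matched on expression and genomic length had a median of -0.35.

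Of 26 genes for collagens and other extracellular matrix proteins, 12 fell in old muscle and 14 did not pass over all genes. Adjusted over the list alone 21 fell, and all 26 lay below 0 (median log2 -0.67). Col3a1 fell from 149.8 ± 41.0 to 41.5 ± 8.17 CPM (log2 -1.87, adjusted p = 6.0e-04), Col5a2 by 1.52 on the log2 scale (adjusted p = 0.0010) and the collagen-binding protein Sparc from 274 ± 10.8 to 144 ± 0.592 CPM (log2 -0.93, adjusted p = 0.0017). The fall was also seen relative to all genes with library size alone (median -0.68). Camera gave adjusted p = 1.8e-13, with adjusted p = 0.699 with an estimated correlation and 0.132 in fry. Of 12 fibro-adipogenic progenitor genes 2 fell, Mfap5 (log2 -1.03) and Dpt (log2 -0.65), or 3 adjusted over the list alone (median -0.19, camera adjusted p = 0.137). Mfap5 lost its call without young sample 2 (adjusted p = 0.15), and Dpt without old sample 1 (0.112), old sample 2 (0.07) or young sample 2 (0.269). Of 5 tendon genes Thbs4 fell (log2 -0.97, adjusted p = 0.0084), also adjusted over the list alone, where the median was 0.042, the mean -0.061 and camera's direction down (adjusted p = 0.686). Of 9 smooth muscle and pericyte genes Tagln fell (log2 -0.75, adjusted p = 0.038), or 3 adjusted over the list alone (median -0.16, camera adjusted p = 0.152). The call of Tagln was lost without old sample 1 (adjusted p = 0.0693), old sample 2 (0.0981) or young sample 2 (0.176). With library size alone the medians of the progenitor and smooth muscle lists turned to 0.064 and 0.062, below the shift of all genes.

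Igkc, Igha and Jchain, transcripts of antibody-secreting cells, were found almost solely in old muscle, whereas the heavy chain Ighm was found at both ages. The light chain constant region Igkc had 664 UMIs in the old samples and 1 in the young, a ratio per total UMIs of 836 (exact 95% counting interval 149.6 to 33074), and was seen in 207 of 4066 old and 1 of 3619 young spots. The heavy chain Igha had 211 against 1 UMIs (ratio 266, interval 47.2 to 10544) and the joining chain Jchain 90 against 5 (ratio 22.7, interval 9.36 to 71.5). All 3 genes rose in edgeR, at adjusted p of 9.2e-05 for Igkc, 7.0e-05 for Igha and 6.0e-04 for Jchain. Igha lay at 37.5 and 1.53 CPM in the sections of old sample 1 and at 0.612 and 28.9 CPM in those of old sample 2, so that 1 section of each sample carried most of its rise. Ighm had 87 and 368 UMIs in the old samples and 37 and 120 in the young (adjusted p = 0.077). So 3 of the 4 measured B and plasma cell genes rose over all genes and 4 adjusted over the list alone (camera adjusted p = 1.9e-06, and adjusted p = 0.699 with an estimated correlation). None of the 11 T and natural killer cell markers reached the count filter.

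Antigen presentation and interferon response genes lay higher in old muscle, with 15 of 17 above 0 (median log2 0.53). Of them 1 passed over all genes, the class I molecule H2-K1 (78.9 ± 8.36 to 127 ± 7.07 CPM, log2 0.68, adjusted p = 0.020), and 4 rose adjusted over the list alone. Camera gave adjusted p = 3.6e-04, and adjusted p = 0.772 with an estimated correlation. Among macrophage markers DESeq2 called 0 of the 11 with an adjusted p there. Of all 16 edgeR called 0 (3 at an unadjusted p under 0.05), also adjusted over the list alone. Their median was -0.099 (camera adjusted p = 0.508), which turned to 0.17 with library size alone. Of 5 red blood cell genes it called 0 (2 at an unadjusted p under 0.05, 0 in DESeq2), 2 rose adjusted over the list alone and all 5 lay above 0 (median 0.52, camera adjusted p = 0.033, and adjusted p = 0.772 with an estimated correlation), a call lost without old sample 2 (0.0861) and young sample 1 (0.505). It was also lost with library size alone (0.0621) and with sections as replicates (0.0909). In senescence 1 of 11 genes, the chemokine Ccl2, fell (log2 -2.04, adjusted p = 0.020, but log2 -1.37 and adjusted p = 0.296 without young sample 2), also adjusted over the list alone (median -0.43, camera adjusted p = 0.508).

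Among sarcomere genes the fast-twitch list held 2 rises of 14, Mybpc2 (log2 0.55) and Actn3 (log2 0.51), a binding protein and an actinin of fast fibres, while adjusted over the list alone 5 rose and 2 fell. Both calls were lost without old sample 1 (adjusted p of 0.193 for Mybpc2 and 0.3 for Actn3), old sample 2 (0.201 and 0.26) or young sample 2 (0.0779 and 0.0738), and in spots matched on the Myh4 share. The list's median was -0.058, its mean 0.068 and camera's direction up (adjusted p = 0.808), and the median turned to 0.18 with library size alone. In the slow-twitch list 3 of 13 fell, also adjusted over the list alone: Csrp3 (log2 -1.64), the stretch-responsive Ankrd2 (123 ± 25.6 to 51.7 ± 0.934 CPM, log2 -1.26, adjusted p = 0.0014) and Myoz2 (log2 -0.72, adjusted p = 0.045). In spots matched on the Myh4 share Csrp3 was at log2 -0.94 (adjusted p = 0.012), Ankrd2 at -0.69 (adjusted p = 0.019) and Myoz2 at -0.042 (adjusted p = 0.95). Myoz2 also lost its call without old sample 1 (log2 -0.60, adjusted p = 0.142) or young sample 2 (log2 -0.47, adjusted p = 0.298). The slow-twitch median was 0.40 and the mean 0.050, with 8 genes above 0 and 5 below, while camera's direction was down (adjusted p = 0.546). In spots matched on the Myh4 share the median of the list was 0.94, so the 3 falls do not stand for the list. Of 20 calcium handling genes 2 rose, the calcium channel subunit Cacng1 (log2 0.79, adjusted p = 0.014) and the ryanodine receptor Ryr1 (log2 0.52, adjusted p = 0.045), and adjusted over the list alone 2 rose and 1 fell (median 0.034, camera adjusted p = 0.686). Cacng1 was at adjusted p = 0.0542 without young sample 2, and Ryr1 at 0.253, 0.163 and 0.139 without old sample 1, old sample 2 and young sample 2.

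Few genes of innervation passed the test. Of 15 neuromuscular junction genes 1 rose, also adjusted over the list alone, and the median was 0.29 (camera adjusted p = 0.028, and adjusted p = 0.772 with an estimated correlation), a call lost without old sample 2 (0.115) or young sample 1 (0.264). It was also lost among genes of at least 20 CPM (0.315) and in spots matched on the Myh4 share (0.074). Of 7 Schwann cell and nerve genes 2 rose, among them S100b (log2 1.75, adjusted p = 0.039), or 3 adjusted over the list alone (median 0.30, camera adjusted p = 0.119). S100b lost its call without old sample 2 (adjusted p = 0.201), young sample 1 (0.0734) or young sample 2 (0.21). In the denervation response edgeR called 0 of 14 (5 at an unadjusted p under 0.05), also adjusted over the list alone. DESeq2 called 0 of the 5 with an adjusted p there. The median was 0.25 (camera adjusted p = 0.427). Of 18 atrophy, ubiquitin ligase and autophagy genes 2 fell, the metal-binding Mt1 and Mt2, whereas adjusted over the list alone 2 fell and 1 rose. The median of that list was 0.16 and its mean -0.18, with camera's direction up (adjusted p = 0.974). Of 8 integrated stress response genes Chac1 rose, and adjusted over the list alone 1 rose and 1 fell (median -0.050, turning to 0.20 with library size alone, camera adjusted p = 0.653).

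Of 15 immediate early and heat shock genes, which can respond to handling, 4 fell (Hspa1a, Hspa1b, Nr4a1 at log2 -0.79 with adjusted p = 0.0061, and Atf3 at log2 -2.21 with adjusted p = 0.018), or 5 adjusted over the list alone. Without young sample 2 Atf3 was at log2 -1.45 (adjusted p = 0.247) and Hspa1a at log2 -1.73 (adjusted p = 0.0054). Of the list 9 lay below and 6 above 0 (median -0.22, camera adjusted p = 0.026, and adjusted p = 0.772 with an estimated correlation). With library size alone the median was 0.042, or -0.22 relative to the shift of all genes. Its camera call was lost without old sample 2 (0.412), among genes of at least 20 CPM (0.493), with sections as replicates (0.0575) and in spots matched on the Myh4 share (0.0566). Of 1000 matched random lists 90 had as low a median. In the circadian clock edgeR called 0 of 14 genes (3 at an unadjusted p under 0.05), also adjusted over the list alone. DESeq2 called 0 of the 13 with an adjusted p there. All 14 lay above 0 (median 0.28, camera adjusted p = 0.0498, and adjusted p = 0.772 with an estimated correlation), a call lost without old sample 1 (0.407), young sample 1 (0.147) or young sample 2 (0.205). It was also lost with library size alone (0.097) and with sections as replicates (0.243). Among other cell types edgeR called 0 of 6 adipocyte genes (2 at an unadjusted p under 0.05, 0 in DESeq2), of which 2 fell adjusted over the list alone (median -0.74, camera adjusted p = 0.508). It called 0 of 12 endothelial genes (2, and 0 in DESeq2), of which 1 rose adjusted over the list alone (median 0.076, camera adjusted p = 0.557). It called 0 of 5 satellite cell genes (3, and 0 in DESeq2), of which 2 fell adjusted over the list alone (median -0.12, turning to 0.13 with library size alone, camera adjusted p = 0.511). Of 4 measured sex-linked genes it called 0 (1, and 0 in DESeq2), also adjusted over the list alone (median 0.28, camera adjusted p = 0.508). DESeq2 gave an adjusted p for only 4 adipocyte, 2 satellite cell and 3 sex-linked genes, and for all 12 endothelial genes. Xist had 0 UMIs in all 7 sections, which allows up to 1.25 CPM in the shallowest, and the Y-linked Ddx3y had 277 to 400 UMIs in each. Camera called 13 of 31 lists at the preset correlation, 0 with an estimated correlation (2 at an unadjusted p under 0.05) and fry called 0 (5 at an unadjusted p under 0.05). So few samples leave camera with an estimated correlation hardly able to call any list. Its 0 calls decide nothing about single lists and leave the calls at the preset correlation unchecked. Medians were also set against 1000 random lists each, matched on expression and genomic length. As low lay 1 for senescence, 0 for adipocytes and matrix and 21 for fatty acid oxidation. As high lay 0 for antigen presentation, atrophy, red blood cells and B and plasma cells. The circadian clock had 1 as high, slow-twitch 4 and neuromuscular junction 13. Other lists compared lay within the central 95 percent or are given above. Genes of a list can vary together, so these are no p-values.

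**Figure D3:**
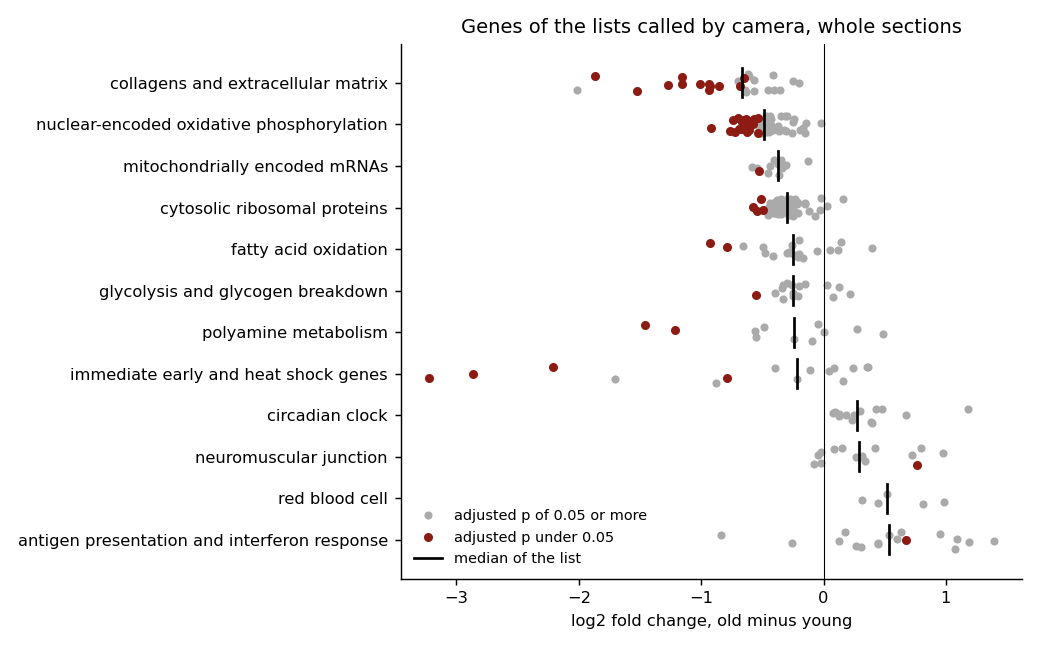
Log2 fold change, old minus young, of each measured gene in 12 of the 13 lists called by camera (the B and plasma cell list is left out), with dark red points for genes at an adjusted p under 0.05 and a line at each list's median. All 26 matrix genes and all 58 nuclear-encoded oxidative phosphorylation genes lie below 0. The median of the immediate early list is 0.042 with library size alone, or -0.22 relative to the shift of all genes.

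Within each section, Myh4-high and Myh4-low spots were compared to see which transcripts followed fibre type across the muscle. Relative to scaled total counts, Myh4-high spots held more mRNA of the polyamine enzymes Amd1, Smox and Odc1. The same was true of 15 of 25 matrix and 10 of 13 macrophage genes. On that scale Myh4-low spots held more of 57 of 58 nuclear-encoded oxidative phosphorylation, 19 of 20 fatty acid oxidation and 6 of 8 slow-twitch genes. Camera called these lists at the preset correlation but 0 of 29 with an estimated correlation, at adjusted p of 0.24 or more. Between zones 1313 of 7951 genes differed, 622 higher in the Myh4-high zone and 691 lower (2108 at an unadjusted p under 0.05), and DESeq2 called 704. Amd1 was the named gene with the largest difference upward (135 ± 73.6 against 36.9 ± 13.9 CPM, n = 4, log2 1.91, SE 0.13, adjusted p = 2.7e-12), followed by Amd2 (log2 1.78), the muscle AMPK subunit Prkag3 (log2 1.74), Pi16 (log2 1.69), Dkk3 (log2 1.67), Ighm (log2 1.66), Retnla (log2 1.63) and myostatin, Mstn (log2 1.60), all at adjusted p of 1.2e-05 or less. Retnla, a protein of alternatively activated macrophages, was at log2 0.93 (adjusted p = 2.7e-06) without young sample 2 and had an adjusted p of 0.142 in DESeq2. The myosin light chain Myl3 was lower by the most (log2 -3.54, adjusted p = 3.7e-19), then Myoz2 (log2 -2.97), Ankrd2 (log2 -2.72), Csrp3 (log2 -2.62), the ketone body enzyme Bdh1 (log2 -2.56), Gm15543 (log2 -2.22), Lmod2 (log2 -2.18) and Smtnl1 (log2 -2.09). The zones differed in depth, with median UMIs per spot of 2020.5 to 2765.5 in the Myh4-high and 3047 to 4934 in the Myh4-low zone of the samples. A higher CPM in the Myh4-high zone therefore need not mean more molecules per spot. Between 115 and 436 spots of a sample lay within 0.05 of a zone limit in Myh4 share.

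The polyamine list was higher in the Myh4-high zone. Of 10 measured genes 5 were higher, or 6 adjusted over the list alone: besides Amd1 and Amd2, Smox (107 ± 64.0 CPM, log2 1.29, adjusted p = 4.8e-10), Odc1 (59.6 ± 12.0 CPM, log2 1.19, adjusted p = 1.5e-08) and Sms (68.6 ± 12.9 CPM, log2 0.88, adjusted p = 2.6e-06). Oaz1 (log2 0.18, adjusted p = 0.074), Azin1 (log2 0.14), Srm (log2 0.061), Sat1 (log2 -0.14) and Oaz2 (log2 -0.24) did not pass. The list's median was 0.53 (camera adjusted p = 5.6e-04, adjusted p = 0.24 with an estimated correlation, fry adjusted p = 0.016).

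Among the other lists, 57 of 58 nuclear-encoded oxidative phosphorylation genes (median log2 -0.57, camera adjusted p = 4.0e-27), 19 of 20 fatty acid oxidation genes (median -0.99, 8.7e-20), 12 of 13 mitochondrially encoded mRNAs (median -0.75, 9.1e-12), 6 of 8 slow-twitch genes (median -2.58, 7.1e-08), 6 of 12 endothelial genes (median -0.38, 3.7e-04) and 5 of 5 red blood cell genes (median -0.79, 2.2e-04) were lower in the Myh4-high zone, the second value of each being camera's adjusted p. Adjusted over the list alone these counts were 57, 20, 13, 6, 7 and 5. Higher there were 15 of 25 matrix genes, with 1 lower (median 0.53, 2.3e-07), 10 of 13 macrophage genes (median 0.79, 6.4e-07), 8 of 11 fibro-adipogenic progenitor genes (median 0.62, 2.0e-06), 11 of 20 calcium handling genes, with 1 lower (median 0.38, 5.2e-05), 11 of 11 fast-twitch genes (median 0.55, 9.3e-08), and 51 of 75 ribosomal protein genes, with 1 lower (median 0.23, 1.8e-09). The myosin heavy chains that set the zones were left out of the fast-twitch list. Adjusted over the list alone the higher counts were 18, 11, 10, 11, 11 and 62. With an estimated correlation 0 of 29 lists passed in camera (4 at an unadjusted p under 0.05), at adjusted p of 0.24 or more, while fry called 15.

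**Figure D4:**
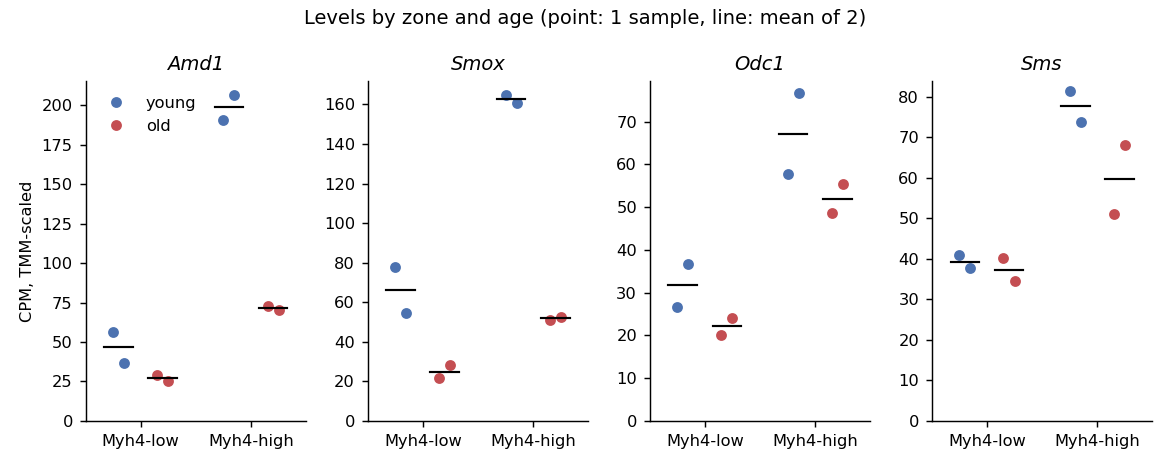
TMM-scaled CPM of Amd1, Smox, Odc1 and Sms in the Myh4-low and Myh4-high zones, with a point per sample (2 old, 2 young) and a line for the mean of each age. Amd1 lies at 70.3 and 72.9 CPM in the Myh4-high zone of old muscle and at 191 and 206 CPM in that of young muscle.

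The age effect was then tested within each zone. In the Myh4-high zone 111 genes rose and 163 fell in old muscle, of 7758 tested (1341 at an unadjusted p under 0.05; 133 genes in DESeq2), and in the Myh4-low zone 142 rose and 175 fell of 8427 (1505 at an unadjusted p under 0.05; 192 in DESeq2). Igkc and Igha rose in the Myh4-high zone (adjusted p of 1.5e-09 and 2.2e-08), together with Cyp26b1 (log2 3.70), the phosphatase Dusp10 (log2 1.99) and Ces1d (log2 1.89). The largest falls there among genes of at least 20 CPM were Nr4a3 (log2 -3.98), Mt2 (log2 -3.18), Nmrk2 (log2 -2.90), Mt1 (log2 -2.63) and the interferon-inducible Ifi205 (log2 -2.10). Among genes of at least 20 CPM in the Myh4-low zone, Ostn (log2 3.56), Cyp26b1 (log2 3.18), Pfkfb3 (log2 2.56), Chac1 (log2 2.12) and Ces1d (log2 1.99) rose most, and Nr4a3 (log2 -2.91), Mt2 (log2 -2.72), Hspa1a (log2 -2.45), Tfrc (log2 -2.33) and Mettl21c (log2 -1.84) fell most. Igkc rose in the Myh4-low zone as well (log2 6.78, adjusted p = 0.0020), with old samples at 4.89 and 53.5 CPM. Its interaction did not pass (adjusted p = 0.849), and Igha had no test in the Myh4-low zone. Smox fell in both zones (log2 -1.59, adjusted p = 2.5e-06, and log2 -1.35, adjusted p = 0.0028). Amd1 fell in the Myh4-high zone (log2 -1.42, adjusted p = 5.8e-06) and had log2 -0.70 (adjusted p = 0.115) in the Myh4-low zone, but the difference between the zones did not pass (log2 -0.78, adjusted p = 0.324; for Smox log2 -0.30, adjusted p = 0.846). The value of Amd1 in the Myh4-low zone depended on the zone limits. It passed with zones split at the median (log2 -0.91, adjusted p = 0.017) or at a Myh4 share of 0.8 (log2 -1.22, adjusted p = 0.0012). It did not pass with at least 10 Myh UMIs and no UMI minimum (0.1045), among genes of at least 20 CPM (0.101) or with sections as replicates (0.0839). With each sample left out it lay between log2 -1.08 and -0.42. The zones did not hold the same fibre make-up at both ages: the Myh4 share was 93.6% ± 0.954 in old against 88.4% ± 1.03 in young in the Myh4-high zone, and 50.2% ± 1.17 against 29.8% ± 5.24 in the Myh4-low zone. Leaving out old sample 1 gave 122 genes in the Myh4-high and 121 in the Myh4-low zone, young sample 1 gave 613 and 830, and young sample 2 gave 209 in the Myh4-low zone. Without old sample 1 Cyp26b1 was at log2 0.94 (adjusted p = 0.706) in the Myh4-high and 1.09 (adjusted p = 0.274) in the Myh4-low zone, and Pfkfb3 at 1.39 in the latter. Without young sample 2 Dusp10 was at log2 1.24 and Ces1d at 3.01 in the Myh4-high zone, and Hspa1a at -1.56 in the Myh4-low zone. The interaction of Dusp10, at log2 0.83 (adjusted p = 0.142) in the Myh4-low zone, did not pass either (log2 1.18, adjusted p = 0.378).

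Few genes had an age effect that differed between the zones. The interaction passed for 9 of 8902 genes (632 at an unadjusted p under 0.05), and for 1 of these, Nmrk2, in DESeq2. With the zones cut at a Myh4 share of 0.8 it passed for 6 genes, 3 of them shared with these 9. Nmrk2 fell more in the Myh4-high zone (log2 -2.90, SE 0.18) than in the Myh4-low zone (log2 -1.41, SE 0.16), a difference of -1.51 (SE 0.17, adjusted p = 7.9e-07). In young muscle its level was 328 and 474 CPM in the Myh4-high and 349 and 340 CPM in the Myh4-low zone, and in old muscle 49.8 and 54.3 against 131 and 123 CPM. The thioredoxin-binding protein Txnip was the 1 gene with a higher age effect in the Myh4-high zone (difference 0.66), and Malat1, Hba-a1, Vim, Hba-a2, Dkk3, Ighm and Pvalb had a lower one. Nmrk2 kept its call without each of the samples in turn, and each of the other 8 genes lost its call without at least 1 of them. The count was 2 without old sample 1 and 20 without young sample 1.

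Clustering of spots gave 10 regions. Regions 1 to 4 held 27.4, 21.6, 18.0 and 15.9% of spots and were nearly of 1 age each, with 96.5, 8.11, 4.07 and 93.3% of their spots from old muscle. Since genes that differ with age lead them (among others Cyp26b1 and Ostn in region 1, Amd1 and Nr4a3 in region 2, Csrp3 and Ankrd2 in region 3, and Pfkfb3 and Igkc in region 4), their shares are not compared. With each spot thinned to 500 UMIs, clustering gave 5 regions (adjusted Rand index 0.245) and this near separation by age was lost. Regions 1 and 2 then had no match at a Jaccard index of at least 0.3, and the cluster closest to both (0.299 each) held 33.9% of old and 35.5% of young spots. That closest to region 3 held 14.7 and 37.2%, and that closest to region 4 held 40.3 and 19.4%. The other regions mixed both ages. Regions 7 to 10 also had no match after thinning, and the cluster closest to each was that closest to region 6. Region 5, with the red blood cell genes Hbb-bt, Hbb-bs, Hba-a1 and Alas2 among its leading genes, held 6.10% ± 0.317 of old and 5.41% ± 2.62 of young spots (n = 2 each). Region 6, led by Cyp2e1, Cytl1, Cfd, Ccl21a and Hp, held 5.51% ± 0.118 and 5.92% ± 1.40. Region 7, led by Ano4 and by the endplate genes Colq, Chrna1 and Chrne, with Hs6st2, held 2.10% ± 0.134 and 1.44% ± 0.488. Region 8, led by Ugt8a, Fam178b, Cntf, S100b and Mbp, genes largely of myelinating Schwann cells, held 1.33% ± 0.830 and 1.25% ± 0.0339. Region 9 (Tigd4, Ankrd1, Col22a1, Myh3 and Map1a) held 1.25% ± 0.277 and 1.38% ± 0.887, and region 10 (Myl10, Myh7b, Fam240b, Tnnt1 and Myh6) held 0.736% ± 0.146 and 0.717% ± 0.109. These differences were not tested, and an exact permutation test of 2 samples against 2 cannot give a p under 0.333.

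**Figure D5:**
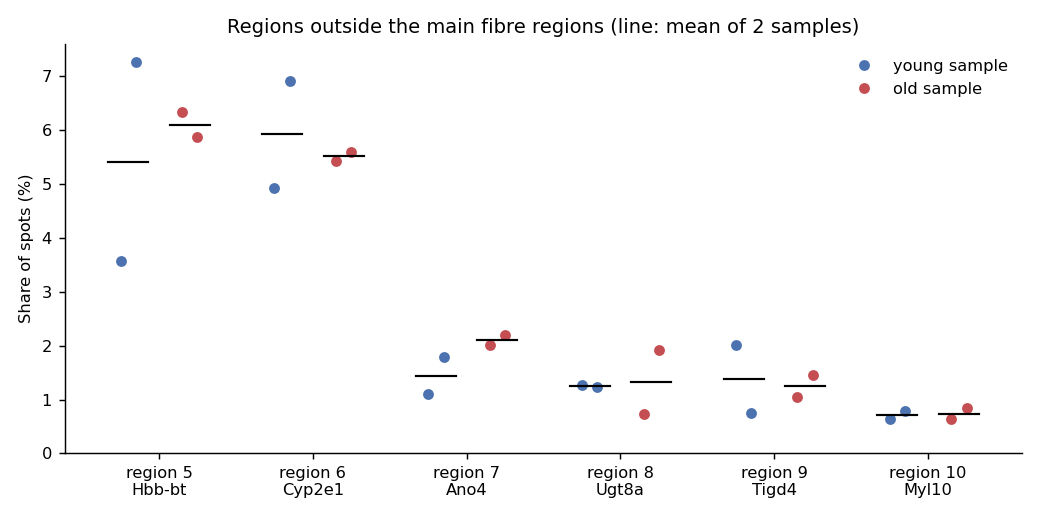
Share of spots (%) in regions 5 to 10, each named with its first leading gene, with a point per sample (2 old, 2 young) and a line for the mean of each age. Region 7, led by endplate genes, holds 2.10% of old and 1.44% of young spots on average, with no test of the difference.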

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

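The tests of spots matched on the Myh4 share, of the summed Amd1 and Amd2 counts, of the immediate early genes and of other splits of the samples were chosen only after the results were seen.

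In 9 genes the age effect differed between the Myh4-high and the Myh4-low zone by the interaction test (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p from 7.9e-07 to 0.048). The differences in log2 age effect were -1.51 for Nmrk2, 0.66 for Txnip, -0.56 for Malat1, -0.60 for Hba-a1, -0.92 for Vim, -0.53 for Hba-a2, -2.77 for Dkk3, -2.05 for Ighm and -0.49 for Pvalb. In the Myh4-low zone of young samples 1 and 2, Dkk3 lay at 1.48 and 0.965 CPM and Ighm at 0.742 and 2.90 CPM. These levels are near the floor, so the size of both differences rests on few UMIs. Without old sample 1 the adjusted p was 0.322 for Txnip, 0.831 for Malat1, 0.216 for Vim, 0.216 for Hba-a2, 0.41 for Dkk3, 0.216 for Ighm and 0.831 for Pvalb. Hba-a1 was at -0.35 (adjusted p = 0.537) without old sample 2 and Pvalb at -0.18 (adjusted p = 0.556) without young sample 2. Without young sample 2 Ighm was at -3.05 (adjusted p = 0.447), and without young sample 1 Pvalb was at -0.79. Ighm lost its call without each sample in turn. With the zones cut at a Myh4 share of 0.8 at both ages, Nmrk2 (-1.20), Txnip (0.54) and Malat1 (-0.43) kept their calls. The other genes lost theirs. Dkk3 was at -0.77 (adjusted p = 0.703), Ighm at -0.15 (0.971), Vim at -0.53 (0.249) and Pvalb at -0.23 (0.257). Hba-a1 and Hba-a2 were at -0.41 (0.0525) and -0.38 (0.0542). The zones held different Myh4 shares at the 2 ages, and groups of 2 samples are too small to be searched for single samples far from the others.

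Amd1 and Smox were lower in old muscle. The higher Myh4 share of old muscle argues in the other direction, since both genes were higher in Myh4-high spots, and in spots matched on that share the smaller of both log2 differences was -1.60. Reads moved from Amd1 to its copy Amd2 would leave their sum unchanged, but the sum fell by 1.04 on the log2 scale. A response of the young muscles to stress or handling could raise both genes there, and stays open. The immediate early and heat shock genes went both ways (9 below and 6 above 0, median -0.22), but the 4 that passed the test all fell. The difference of both genes exceeded the spread between the capture areas of an age, and an effect of age remains a hypothesis.

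Nuclear-encoded oxidative phosphorylation mRNAs had a median log2 difference of -0.48 in old muscle. In spots matched on the Myh4 share their median log2 difference was -0.35, so fibre type by this measure may account for part of that median but not for all of it. None of 10000 random lists matched on mean expression and genomic length had as low a median (percentile 0), although their own median of -0.26 shows that part of the fall was shared by such genes. Genomic length is not transcript length, and tissue handling and age remain open.

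Igkc, Igha and Jchain were seen almost solely in old muscle, unlike Ighm, which had 157 UMIs in young and 455 in old muscle. Blood left in the sections would place Igkc, Igha and Jchain in the spots richest in haemoglobin, but their summed level there was at most 1.16 times that of other spots in the old samples. The haemoglobin-rich spots held 39 and 55 of these UMIs in old samples 1 and 2, and 1 spot held up to 116. The ratio can therefore hang on few spots and argues only weakly against blood. The 10 richest spots of each old section held at least 64.6% of the UMIs of these 3 genes. A few places with plasma cells had been predicted to give this. Such cells carried in blood would also put most UMIs in few spots, so this outcome cannot tell the sources apart. Spot positions were not used, so it is not known whether these spots lie together. That age sets how many such spots a muscle holds is a hypothesis that was not tested.

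With sections as replicates edgeR called 911 genes with age, and at most 14 in any other of the 35 splits of the 7 sections, but 6 of these share a capture area in pairs and are not independent. Of the splits that keep capture areas whole 1 of 3 gave as many (911 genes, and at most 0 in any other), and 3 splits are too few for a share under 0.05. For the zones 1 of 8 splits gave as many (1313 genes, and at most 0 in any other), and 8 splits are too few for a share under 0.05.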

How the results depend on the processing

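The spots matched on the Myh4 share, the removal of section 2 of old sample 1 and the zones within each age alone were chosen only after the results were seen. The count of 442 genes with age was 1058 with no filter beyond 1 count, 279 at a mean of at least 20 CPM, 911 with sections as replicates, 1423 in limma voom with sections and the capture area as a random block, 780 in limma with spots scaled to 1 total (both change the test as well), and 149 to 790 with each sample left out, where the lone sample of an age is assumed to vary like the others. The 13 lists were 0 with an estimated correlation, 0 in fry and 8 at a mean of at least 20 CPM. Between zones the 1313 genes were 704 in DESeq2 and 759 in old samples alone. Within the Myh4-high zone 274 genes were 133 in DESeq2 and 122 to 613 with each sample left out, and within the Myh4-low zone 317 were 192, 121 to 830 and, with sections as replicates, 718. The 9 interactions were 16 when split at the median, 1 in DESeq2, 31 at a mean of at least 20 CPM, 5 with sections and 2 to 20 with each sample left out. In the random block the consensus correlation of sections in a capture area was negative (-0.148). Its 1423 genes therefore make no allowance for sections of an area being alike. Except where fewer genes or samples entered, the cause was not tested.

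Of the named single-gene values, the sign turned for polyamine genes that did not pass the test. For age, Srm was at 0.19 with library size alone, 0.010 with sections, 0.072 with the random block, 0.15 with spots scaled, 0.037 without section 2 of old sample 1 and -0.44 to 0.23 with each sample left out. Sat1 was at -0.014 in DESeq2, -0.0074 with its size factors, -0.0080 with no filter, -0.0025 without mitochondrial, red blood cell and ribosomal genes in the library size, -0.057 without that section and -0.10 to 0.061 with each sample left out. Oaz1 was at 0.14 with library size alone, 0.00081 at a mean of at least 20 CPM and 0.15 with spots scaled, where Sms was at 0.038. Between zones Srm was at -0.31 in old samples alone and -0.30 to 0.18 with each sample left out, and Sat1 at 0.15 in young samples alone. Of all called genes, Mt1, higher in the Myh4-high zone (log2 0.42, adjusted p = 0.021), was at -0.24 (adjusted p = 0.612) in old samples alone, and Actc1, lower with age in the Myh4-low zone (log2 -1.38, adjusted p = 0.039), was at 0.091 (adjusted p = 0.96) without young sample 2; both were named after their values were seen. The cause was not tested. Of the other single-gene values with age 731 kept direction and side of the threshold, 34 lost the call and 11 gained it. Of those of genes from lists with few calls 247 kept it and 81 lost it. Of these 19 genes, besides samples left out, 9 lost their call in spots matched on the Myh4 share, 8 with spots scaled to 1 total, 7 with library size alone, 7 without section 2 of old sample 1, 5 after thinning, 4 in DESeq2 (of 16 with an adjusted p there), 4 with sections (of 18), 2 at a mean of at least 20 CPM (of 12) and 1 with the random block (of 18).

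Region 6 held 4.76% of old spots at resolution 0.3, 3.90% at 0.8, 3.69% with no UMI minimum and 4.67% after thinning, and 4.30% of young spots at 0.8 and 3.46% after thinning, where the matched cluster (Jaccard index 0.308) was also the closest to regions 7 to 10. Region 8 held 1.30% and 1.43% of young spots at 0.3 and 0.8. Of regions 5 to 10, those with no match (Jaccard index under 0.3) gave no value.

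With the replicate number as a block (replicate block), 869 genes and 13 lists were called. The numbers do not pair the samples (correlation of deviations 0.092, over only 2 pairs). Depth limits which genes can be tested: 10840 of 32285 features passed the count filter with age. Thinning each sample to the lowest total gave 405 genes against 442. At these depths and sample numbers 22 percent of simulated changes of 0.5 log2 units were recovered with age, and the recovery was not simulated at other depths.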

Other observations

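All values of this part were chosen only after the results were seen.

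In regions 5 to 9 the pooled levels of Amd1 and Smox were lower in old than in young spots. In region 10, with few counts, Amd1 was at 42.7 CPM (4 UMIs) in old and 30.2 (3 UMIs) in young spots and Smox at 21.3 and 20.1. Both old samples lay below both young samples in regions 5 to 9 for Smox, but for Amd1 in region 6 alone. In that region, led by Cyp2e1, Cytl1 and Cfd, Amd1 was at 48.8 CPM (exact Poisson 95% interval 31.6 to 72) in old and 133 CPM (109 to 161) in young spots, and Smox at 50.8 (33.2 to 74.4) and 117 CPM (94.1 to 143). In region 7, led by endplate genes, Odc1 was at 122 CPM (80.9 to 176) in old and 119.9 (80.3 to 172) in young spots. Of the 664 Igkc UMIs of old muscle 197 lay in region 6, at 385 CPM (333 to 442), with 152 CPM in old sample 1 and 585 CPM in old sample 2. In region 8, led by genes largely of myelinating Schwann cells, Igkc was at 561 CPM (427 to 724) over the old samples. Its 59 UMIs there all came from old sample 2 (713 CPM), and 0 UMIs in old sample 1 allow up to 134 CPM. These intervals cover counting error only, and no difference between the ages was tested.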
